A study of Anguilla anguilla with 3 samples.

How the data were processed

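Ovary RNA was measured in 1 yellow, 1 prepubertal silver and 1 post-spawning matured European eel. Per the labels' protocols, tissue from 3 parts of each gonad was pooled per eel, total RNA was extracted, and an Illumina mRNA library was made from 10 micrograms of it. Per the file headers, the authors predicted genes with Augustus, named them from protein similarity with Blast2GO, and aligned and counted reads with CLC bio software. The submitters' processing notes also list CASAVA, TopHat2 2.0.5, SAMtools 0.1.18, HTSeq and DESeq, with no role or order, and the genome build is not given in the sources used here. Names are therefore those of the most similar protein, and several predicted genes can share one.

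The deposited table holds 45974 genes, of which 32673 (71.1%) have a name, and it pairs each name with the authors' gene identifier. The counts are the authors' corrected total reads per gene, whole numbers that include reads with several alignments distributed by the CLC method per the file headers, and the table also gives the authors' counts of uniquely aligned reads. The RPKM values are the authors' corrected reads divided by longest transcript length and library total, per the file headers. The fold, a ratio of the later to the earlier stage, and its log2 value were deposited by the authors from DESeq on the corrected counts, with the log2 adjusted to avoid infinite values per the file headers. The p-values and adjusted p-values were deposited by the authors from the same tool, which with no replicates took the variance from the 3 libraries per the file headers. The last line names no gene and holds the column totals, which equal the sums over genes. It was left out together with 1 blank line, and no reads belong to either.

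Library totals were 27811764 (yellow), 41426808 (silver) and 30137882 (matured) corrected reads, of which 97.9%, 98.2% and 98.2% were unique alignments, and 36226, 37329 and 36622 genes had reads. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (0.957, 0.910 and 1.15) to CPM, in which each library has a common size. The log2 ratio of a gene was taken after adding 1 CPM to both libraries, which shrinks the ratios of low genes, and a gene was counted as higher or lower when that ratio reached 4-fold with at least 10 CPM in the higher library. Folds of single genes are ratios of scaled counts without that addition, with an exact conditional binomial (Clopper-Pearson) 95% interval. Where 1 library had no reads the fold is a lower bound against a floor of 3 counts in that library, which is 0.113 CPM in the yellow, 0.0795 in the silver and 0.0867 in the matured library. Reads of a PCR-amplified library are not independent molecules, so intervals and floors cover counting error only. With 1 eel per stage no p-value was computed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

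The comparisons, thresholds, 18 gene lists and 10 marker lists were fixed before the data were examined. Of the 751 list entries 612 matched a gene of the table through a map from protein names to symbols, and all rows that share a matched name were used, so 79 rows belong to more than 1 list. The oocyte list includes zp genes and so overlaps the egg coat list. No row matched star or vtg1, which are not analysed here. A list's median was taken over members with at least 1 CPM on average and placed among 10000 random lists of equal size drawn from 20 bins of mean expression over 24571 genes. A list was said to stand apart under percentile 2.5 or over 97.5, which describes these libraries and is no test of the life stages. Genes named in the text were the 10 highest and 10 lowest named genes of each comparison, up to 4 members of each list with the largest log2 ratio and at least 10 CPM, a fixed set of steroidogenic, receptor and oocyte genes, and the 3 most abundant genes of each library. Genes chosen outside this rule are said to be so where they are named.

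The steps were tested on simulated data in which 200 genes of the silver library and 200 other genes of the matured library were changed by known folds against the yellow library. Apart from these changes, each count was drawn from a Poisson distribution around a mean profile shared by all libraries. The simulation held no differences between eels and no trend over transcript length. It therefore covers counting error only and says nothing about false calls between real eels. In the simulated silver versus yellow libraries 0 of 11283 unchanged genes were called, as were 0 of 50 genes changed 2-fold and 0 of 49 changed 3-fold, against 47 of 48 changed 6-fold and 49 of 49 changed 12-fold. Counting intervals covered the true fold of 94.97% of the unchanged genes, and 3 of 100 unchanged lists fell outside the central range. The alternatives planned were DESeq2 1.42.0 size factors, library totals alone, a minimum of 1 CPM, pseudocounts of 0.1 and 5 CPM, a 2-fold threshold, a counting interval wholly beyond 4-fold, the authors' RPKM values, and list members of at least 10 CPM. Those added after seeing the data were unique reads, the authors' deposited fold, the 10 most abundant rows of each library left out, and the trend over transcript length removed.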

Results

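Ovary transcriptomes were sequenced from 3 European eels (Anguilla anguilla), 1 at each of 3 life stages. They were a yellow eel, which is the growing stage, a prepubertal silver eel, which has begun the change towards the seaward migrant, and a matured eel sampled after spawning. RNA of 3 parts of the gonad was pooled for each eel, so every library describes 1 animal. The silver eel came from another lake than the other eels and was taken in December, while the yellow and matured eels came from the same lake in spring. The gene counts summed to 27811764 reads in the yellow library, 41426808 in the silver library and 30137882 in the matured library, over 45974 predicted genes of which 32673 carry a protein name. With 1 eel per stage there is no replicate check, so the differences given are between these libraries. No test was made, and the 95% intervals of folds cover counting error only. Counts of genes at least 4-fold higher or lower use the ratio after adding 1 CPM to both libraries, which is smaller than the printed fold. A gene printed at little over 4-fold may therefore not be counted.

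Egg coat and unnamed transcripts led the yellow and silver libraries. In the yellow library the most abundant rows were g45425 and g452, which have no name, at 24687 and 18401 CPM (reads scaled to a common library size), followed by zp2 (g45297), an egg coat glycoprotein, at 15099.9 CPM. In the silver library zp2 led at 11352 CPM, followed by g45425 at 9409 CPM and the egg coat gene zp3 (g36576) at 9209.6 CPM. In the matured library 3 rows without a name led, g38355 at 21729 CPM, g43702 at 13952 CPM and g43701 at 11282 CPM. The 10 most abundant genes took 11.7% of the reads of the yellow library, 6.84% of the silver library and 11.98% of the matured library.

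The first comparison, silver versus yellow, addresses the ovary before puberty on either side of silvering. The median log2 ratios of the steroid synthesis, cholesterol synthesis and prostaglandin lists stood above those of random lists of genes, with 3, 3 and 5 members at least 4-fold higher in the silver library. For these lists the part of a trend with transcript length could not be told apart. The immune, apoptosis and oxidative phosphorylation lists stood above random lists too, and stayed apart with that trend removed. The egg coat list stood below random lists, with 2 members at least 4-fold lower by the ratio after adding 1 CPM, and all 4 vldlr rows were lower by less than 4-fold. The steroid 17-alpha-hydroxylase gene cp17a (g22995), which opens the route from progestins to androgens, was 11.2-fold higher in the silver library (95% interval 8.84 to 14.3). The epidermal growth factor receptor egfr was 14.4-fold higher (12.3 to 16.99), and choriogenin H (g45063), an egg coat protein, was 18.5-fold lower (17.5 to 19.6).

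Of 12462 genes with at least 10 CPM in the higher library, 460 were at least 4-fold higher and 178 at least 4-fold lower in the silver than in the yellow library. That is 72.1% higher, against 50.8% with the authors' RPKM values, where 322 genes were higher and 312 lower. The highest named genes included asal, described as a mannose-specific lectin, which had no reads in the yellow library and was at least 635-fold higher against a floor of 3 counts. The thymidine kinase kitm was 135-fold higher (71.1 to 296). The uridine-cytidine kinase-like gene uckl1 was 189-fold higher (80.9 to 584) and collectin-11, a soluble lectin of innate immunity named col11, was 29.1-fold higher (23.3 to 36.8). Among the lowest, bhmt1, which remethylates homocysteine with betaine, was 97.4-fold lower (67.6 to 146), akd1 was 356-fold lower (204 to 690) and kif1b, a kinesin motor, was 50.1-fold lower (41.5 to 61.0). The egg envelope gene vmo1 and the T-box factor tbx6 had no reads in the silver library and were at least 349.7-fold and 292-fold lower.

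Steroid synthesis genes had a median log2 ratio of 0.55 over 25 measured members, at percentile 99.2 of random lists matched on expression, and 3 members were at least 4-fold higher and 0 lower. Those 3 were the cp17a rows g22995 and g10692 and the gene s5a1. Besides cp17a, the 5-alpha-reductase gene s5a1 was 4.84-fold higher (4.30 to 5.46) and the side-chain cleavage enzyme cp11a, which makes pregnenolone from cholesterol, was 3.26-fold higher (2.83 to 3.76). The carbonyl reductase cbr1 was 3.85-fold higher (3.69 to 4.02). Not all steps went the same way, since 3bhs (g10190), the 3-beta-hydroxysteroid dehydrogenase, was 1.78-fold lower (1.66 to 1.91). Cholesterol synthesis genes had a median of 0.65 (percentile 99.3, 23 members), with 18 members above 0. The sterol sensor insi1 was 10.4-fold higher (7.48 to 14.8), the lanosterol demethylase cp51a 6.46-fold higher (5.54 to 7.57) and the mevalonate pathway enzyme erg19 4.47-fold higher (4.03 to 4.98), while nsdhl was 3.76-fold lower (3.54 to 3.99). Genes of ovulation and prostaglandins had a median of 0.54 (percentile 99.5, 27 members), with 5 members at least 4-fold higher and 1 lower. Among them the prostaglandin synthase pgh1 was 6.52-fold higher (5.59 to 7.64) and the coactivator-binding gene cite2 11.5-fold higher (9.62 to 13.9), and the growth factor betacellulin, btc, was 11.4-fold lower (8.51 to 15.5).

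Oocyte genes had a median of -0.38 (percentile 0.06, 58 members) and egg coat genes one of -0.44 (percentile 0.72, 20 members, of which 14 were below 0). These lists share zp rows, so they are not separate results. A second zp3 copy (g29228) was 4.85-fold lower (4.40 to 5.36) and zp4 (g8286) 4.01-fold lower (3.82 to 4.22). In contrast, nano1, an RNA-binding regulator of germ cells, was 4.08-fold higher (3.67 to 4.54) and gdf9, an oocyte growth factor, was 1.91-fold higher (1.81 to 2.03). Lipoprotein uptake and yolk processing genes had a median of -0.27 (percentile 0.28, 88 members). Their vldlr rows, which encode the lipoprotein receptor family that takes up yolk precursors, were lower in all 4 copies, by 2.40-fold in g14275 (2.34 to 2.45) and 2.79-fold in g40667 (2.69 to 2.90). The copy g14276 was 2.36-fold lower but only 14.4% of its reads aligned uniquely, so its value is uncertain. The apolipoprotein apoeb (g15956) was 4.59-fold lower (4.30 to 4.91), and the lysosomal protease catz was 4.14-fold higher (3.65 to 4.72).

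Apoptosis and autophagy genes had a median of 0.43 (percentile 99.9, 66 members), with bid, a death agonist of the BCL2 family, 3.92-fold higher (3.61 to 4.26). Oxidative phosphorylation genes had a median of 0.38 (percentile 99.6, 107 members), and meiosis genes one of 0.70 (percentile 98.9, 11 members). The hydration and ion transport list had a median of 0.29 (percentile 97.7, 62 members), in which the water and glycerol channel aqp3 was 4.60-fold higher (3.96 to 5.36). Ovarian somatic cell and sex genes had a median of 0.41 (percentile 98.3, 20 members), with foxl2 (g429), a transcription factor of the granulosa lineage, 3.05-fold higher (2.44 to 3.84). The immediate early gene fos (g12409) was 26.2-fold higher (20.5 to 34.02), and the ribonucleotide reductase subunit rir2 was 7.14-fold higher (6.92 to 7.36). The lists of hormone receptors (-0.05), lipid synthesis (-0.07), matrix remodelling (-0.06), cell cycle (0.05), ribosomal proteins (0.14) and heat shock and stress (0.26) lay inside the central 95% of random lists.

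Among the marker lists of other cells, the immune and erythrocyte lists stood apart. The immune marker list had a median of 0.65 (percentile 100, 59 members), with the chemokine ccl25 23.7-fold higher (17.1 to 33.6) and the receptor tlr2 8.10-fold higher (6.34 to 10.5) in the silver library. The erythrocyte list had a median of 0.59 (percentile 98.9, 14 members), which turned to -0.49 over members of at least 10 CPM, and its globin hbba reached 2.52 CPM in the yellow and 10.1 CPM in the silver library. The reference gene list had a median of -0.27 (percentile 2.19, 33 members), and its member hprt (g3310) was 5.73-fold higher (5.20 to 6.31). With the trend of the log2 ratio over transcript length removed, a choice made after seeing the data, 7 of the 15 lists that stood apart moved inside the central range. The lipoprotein uptake median went from -0.27 to -0.11 (percentile 12.2) and the collagen median from 0.20 to 0.09 (percentile 80.1). Meiosis (0.49, percentile 95.5), cholesterol synthesis (0.43, percentile 97.0), hydration and ion transport (0.20, percentile 95.3), ovarian somatic genes (0.27, percentile 90.5) and erythrocytes (0.47, percentile 96.96) kept most of theirs.

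The second comparison, matured versus silver, sets the eel sampled after spawning against the prepubertal silver eel, which also differed in lake and season. How the matured eel came to maturity was not analysed here. The medians of the collagen, immune, smooth muscle and epithelial lists stood above random lists, with 16, 16, 6 and 5 members at least 4-fold higher in the matured library. The androgen-producing enzyme cp17a and the lipid carrier apoeb were higher too. Transcripts of several oocyte, cell division and cell death regulators and of the prostaglandin genes pgh1 and pe2r3 were lower. The medians of the oocyte and cell cycle lists as wholes lay inside the range of random lists (percentiles 8.09 and 37.3). The gene apoeb (g15956), an apolipoprotein E, was 101-fold higher (94.99 to 107) and reached 3139.8 CPM, cp17a (g22995) was 9.71-fold higher (9.14 to 10.3), and the collagen I gene co1a1 (g7014) was 13.3-fold higher (12.3 to 14.3). The oocyte kinase mos, which holds eggs in meiotic arrest, was 5.07-fold lower (4.95 to 5.20), and rir2 was 14.7-fold lower (14.1 to 15.2).

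Of 12573 genes with at least 10 CPM in the higher library, 281 were at least 4-fold higher and 579 at least 4-fold lower in the matured than in the silver library. That is 32.7% higher, against 57.6% with library totals alone (444 higher and 327 lower). It was 57.7% with the authors' RPKM values (433 and 318), which also rest on library totals. Library totals alone moved the median log2 ratio of all genes from -0.03 to 0.25 here and from -0.05 to 0.18 in matured versus yellow, and values of the matured library are to be read relative to that shift. The highest named genes included afp4, a type 4 ice-structuring protein of the apolipoprotein fold, which was 1419-fold higher (688 to 3529.6). The water channel aqp1 (g214) was 35.4-fold higher (28.6 to 44.46) and clusterin, clus, was 18.6-fold higher (17.004 to 20.5). The immunoglobulin heavy chain gene mucm was 75.95-fold higher (63.2 to 92.0) and the channel-like gene tmc3 690.2-fold higher (236 to 3350.1), from a level of 0.0795 CPM in the silver library. The lowest included casp1, an inflammatory caspase, which was 37.4-fold lower (33.9 to 41.37), and the amino acid transporter subunit 4f2, which was 201-fold lower (78.4 to 741). They also included the histone gene h48, which was 31.7-fold lower (26.7 to 37.9), and col11, which was 28.9-fold lower (23.8 to 35.4). Another immunoglobulin heavy chain gene, hvm63, was 62.1-fold lower (40.8 to 99.3).

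Steroid synthesis genes had a median of 0.55 (percentile 100, 25 members), with 3 members at least 4-fold higher, which were the 3 cp17a rows, and 1 lower, which was s5a1 (5.10-fold, 4.58 to 5.68). The hormone receptor list had a median of 0.08 (percentile 51.6, 42 members), and within it the progesterone receptor prgr was 29.6-fold higher (18.3 to 51.3) and the androgen receptor andr (g5987) 3.60-fold higher (3.17 to 4.10). Ovarian somatic cell and sex genes had a median of 0.81 (percentile 100, 20 members), which turned to -0.32 over members of at least 10 CPM. In it gata6, a transcription factor of steroid-producing cells, was 4.99-fold higher (4.42 to 5.64) and tgfb1 8.09-fold higher (5.96 to 11.2), while the transcription factor sox3 (g1675) was 3.96-fold lower (3.90 to 4.02). Aromatase, cp19a, which makes estrogens, stayed under 1.5 CPM in each library in both of its rows, and the luteinizing hormone receptor lshr (g12514) was at 0.106 CPM in the silver and 1.13 CPM in the matured library.

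Oocyte genes had a median of -0.49 (percentile 8.09, 58 members), inside the range of random lists, with 5 members at least 4-fold lower and 0 higher. The germ cell regulator nano3 was 5.88-fold lower (5.67 to 6.11), the egg coat gene zp1 (g15786) 5.19-fold lower (5.14 to 5.24) and gdf9 3.64-fold lower (3.41 to 3.89). Cell cycle genes had a median of -0.29 (percentile 37.3, 94 members), which turned to 0.04 with library totals alone, and 4 members were at least 4-fold lower, including cyclin B2, ccnb2 (g19131), at 4.79-fold (4.66 to 4.91). Apoptosis and autophagy genes had a median of -0.37 (percentile 1.74, 66 members), with the survival factor mcl1 4.17-fold lower (3.98 to 4.37). The ovulation and prostaglandin list had a median of -0.16 (percentile 29.5, 27 members, of which 13 lay above 0), which turned to 0.15 with library totals alone. In it pgh1 was 12.8-fold lower (10.6 to 15.5) and the prostaglandin E2 receptor pe2r3 10.2-fold lower (9.11 to 11.5).

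Collagen and matrix genes had a median of 1.25 (percentile 100, 72 members), with 16 members at least 4-fold higher and 3 lower. The small proteoglycan lumican, lum, was 18.7-fold higher (14.8 to 23.98) and co1a2 10.6-fold higher (9.94 to 11.3). Matrix remodelling genes had a median of 0.71 (percentile 100, 43 members), in which the stromelysin mmp11 was 10.1-fold higher (8.88 to 11.6) and the gelatinase mmp2 4.05-fold higher (3.59 to 4.58). Lipoprotein uptake and yolk processing genes had a median of 0.29 (percentile 100, 88 members), with lipoprotein lipase, lipl, 18.9-fold higher (14.2 to 25.7). Oxidative phosphorylation genes had a median of -0.07, which stood above random lists of equally abundant genes (percentile 97.8) and turned to 0.26 with library totals alone, and the cytochrome oxidase subunit cox8b was 17.4-fold lower (15.5 to 19.6).

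Among the marker lists of other cells, the immune, smooth muscle, endothelial and epithelial lists stood above random lists, while those of erythrocytes, skeletal muscle, adipocytes, hepatocytes and nerve and glia lay inside their range. The immune list had a median of 1.06 (percentile 100, 59 members), with 16 members at least 4-fold higher and 0 lower, among them coronin, cor1a (g22693), at 18.04-fold (12.5 to 26.8) and plastin-2, plsl, at 15.4-fold (10.5 to 23.4). The smooth muscle list had a median of 0.53 (percentile 100, 35 members), with the smooth muscle actin acta 33.1-fold higher (26.8 to 41.3) and desmin, desm, 93.0-fold higher (42.4 to 255). The endothelial list had a median of 1.05 (percentile 100, 12 members), although the endothelial cadherin cadh5 was 4.67-fold lower (3.89 to 5.65). The epithelial and mesothelial list had a median of 0.74 (percentile 100, 22 members), with the keratin k1c18 (g5911) 6.07-fold higher (5.71 to 6.46). Another k1c18 row, g7586, was at 164 CPM in the yellow, 26.0 in the silver and 22.4 in the matured library. The reference gene list had a median of 0.41 (percentile 100, 33 members), with hprt (g3310) 11.7-fold lower (10.4 to 13.2).

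**Figure D1:**
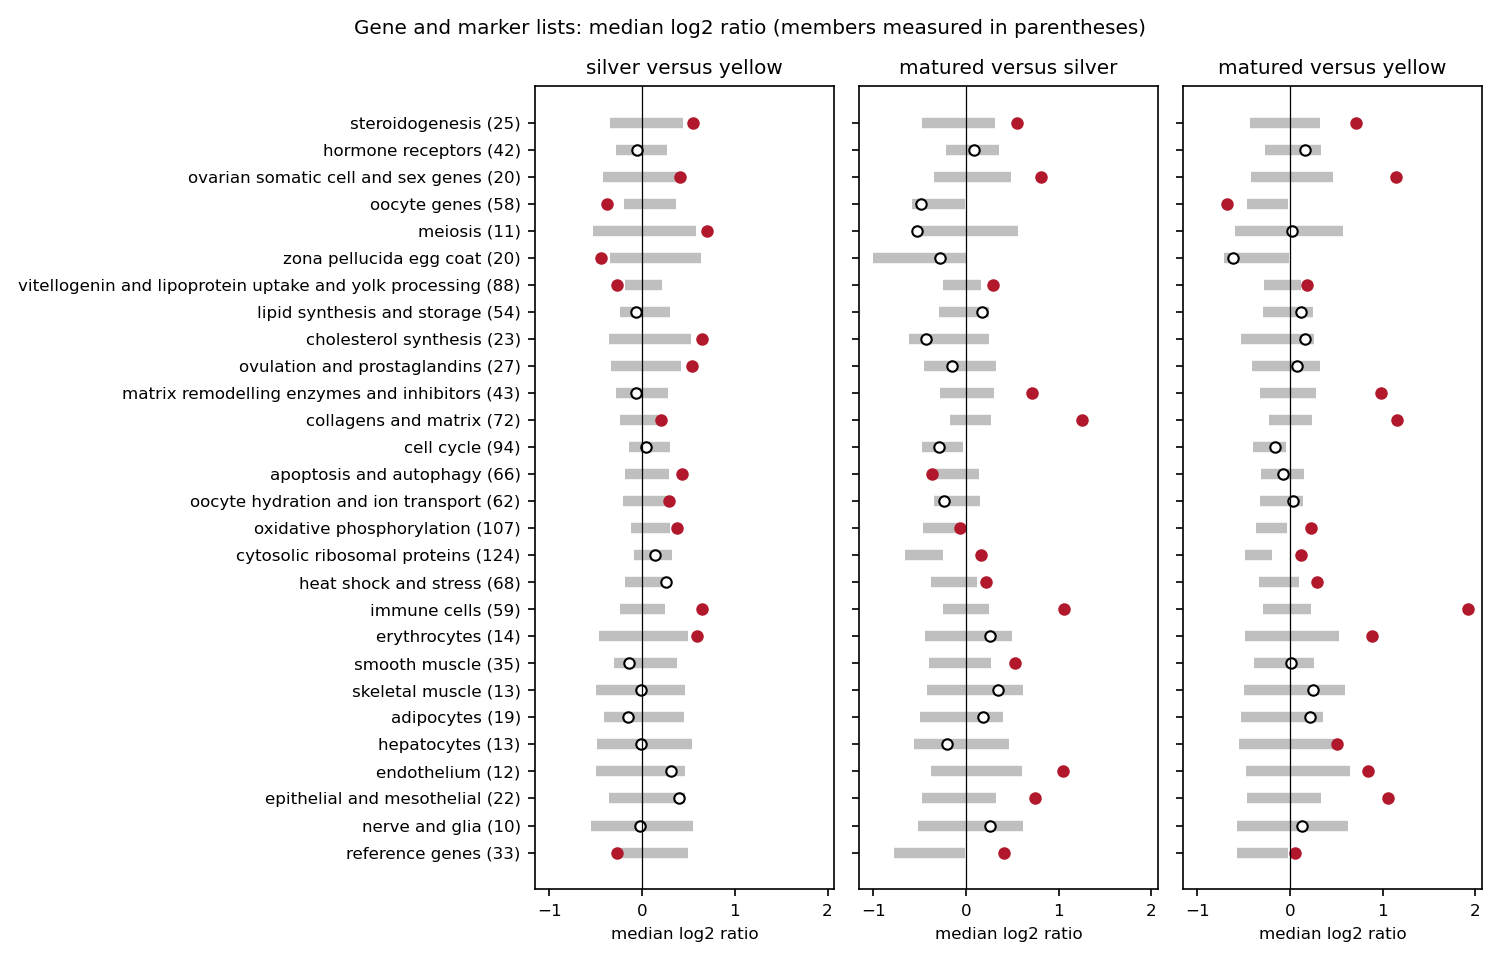
Each panel plots, for 1 comparison, the median log2 ratio of each gene or marker list (circles; number of measured members in parentheses) against the central 95% of medians of 10000 random lists of equal size and expression (grey bars), with filled circles for lists outside that range. The immune list reached 1.92 in matured versus yellow, and the matured versus silver medians of cell cycle (-0.29), oxidative phosphorylation (-0.07), ovulation and prostaglandins (-0.16), hydration and ion transport (-0.23), egg coat (-0.28) and hepatocytes (-0.21) turned positive with library totals alone.

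The third comparison, matured versus yellow, spans the whole series from the growing to the post-spawning ovary. The medians of the immune, collagen, matrix enzyme, ovarian somatic and steroid synthesis lists stood above random lists, with 21, 18, 2, 3 and 5 members at least 4-fold higher in the matured library. That of the oocyte list stood below, with 3 members at least 4-fold lower. The gene cp17a (g22995) was 109-fold higher (86.4 to 138), aqp1 (g214) 97.7-fold higher (64.4 to 156) and the smooth muscle actin acta 95.5-fold higher (62.9 to 153). The interleukin-1 receptor accessory protein il1ap was 34.2-fold lower (31.9 to 36.8) and zar1, an egg protein needed at the start of embryonic life, was 3.92-fold lower (3.85 to 3.995).

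Of 12553 genes with at least 10 CPM in the higher library, 426 were at least 4-fold higher and 325 at least 4-fold lower in the matured than in the yellow library. That is 56.7% higher, against 74.3% with library totals alone (628 higher and 217 lower) and 42.5% at a 2-fold threshold (1426 higher and 1933 lower), where more genes were lower than higher. The highest named genes included the channel-like tmc3, at least 487-fold higher because the yellow library had no reads of it, and the folate receptor folr1 at 52.8-fold (37.3 to 77.4). Among them were also the growth factor antagonist noggin, nogg2, at 40.02-fold (31.1 to 52.3) and the heparin-binding growth factor pleiotrophin, ptn, at 52.3-fold (36.5 to 77.7). The lowest included bhmt1 at 74.0-fold (53.05 to 107), the calcium channel trpv6 at 64.4-fold (40.97 to 107), the glucokinase regulator gckr at 27.6-fold (24.4 to 31.2) and 4f2 at 459.8-fold (179 to 1689.9).

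In this comparison steroid synthesis genes had a median of 0.71 (percentile 100, 25 members), with 5 members at least 4-fold higher and 0 lower. They were the 3 cp17a rows, cp11a at 5.99-fold (5.23 to 6.88) and dhb1, a 17-beta-hydroxysteroid dehydrogenase, at 11.5-fold (9.78 to 13.5). The row 3bhs (g10190) was 1.33-fold lower (1.24 to 1.42). Ovarian somatic cell and sex genes had a median of 1.14 (percentile 100, 20 members), of which 18 lay above 0, with gata6 8.42-fold higher (7.07 to 10.1) and foxl2 (g429) 6.90-fold higher (5.59 to 8.60). The hormone receptor list had a median of 0.16 (percentile 79.8, 42 members), inside the range of random lists, with 3 members at least 4-fold higher. The estrogen receptor copy esr2 (g6324) was 6.48-fold higher (4.84 to 8.85), andr (g5987) 4.95-fold higher (4.19 to 5.89) and prgr 23.7-fold higher (14.2 to 42.7), whereas the esr2 copy g9961 was 1.45-fold lower (1.25 to 1.68). The follicle-stimulating hormone receptor fshr was at 0.752 CPM in the yellow and 1.76 CPM in the matured library, and anti-Muellerian hormone, mis, at 1.503 and 2.92 CPM.

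Oocyte genes had a median of -0.68 (percentile 0, 58 members), of which 48 lay below 0 and 3 were at least 4-fold lower. The germ line RNA-binding gene tdrd1 was 4.23-fold lower (3.97 to 4.51) and zp3 (g29228) 7.25-fold lower (6.44 to 8.19). In contrast, the most abundant zp3 row (g36576) was at 10213 CPM in the yellow and 10099.5 CPM in the matured library, and bmp15, an oocyte growth factor, at 117 and 111 CPM. All 20 measured egg coat rows lay below 0, with a median of -0.61 (percentile 7.09). Collagen and matrix genes had a median of 1.16 (percentile 100, 72 members), with 18 members at least 4-fold higher and 0 lower, among them co1a1 (g7014) at 26.2-fold (23.3 to 29.6) and lum at 46.5-fold (30.3 to 75.4). Matrix remodelling genes had a median of 0.98 (percentile 100, 43 members), with mmp11 37.8-fold higher (28.2 to 51.7), the collagen-degrading protease catk 11.6-fold higher (9.41 to 14.5) and mmp25 7.05-fold lower (5.44 to 9.25). Heat shock and stress genes had a median of 0.29 (percentile 100, 68 members), with the immediate early genes fos (g12409) 16.01-fold higher (12.5 to 20.8) and egr1 22.4-fold higher (12.9 to 42.4). Oxidative phosphorylation (0.22), ribosomal proteins (0.12) and lipoprotein uptake (0.18) also stood above random lists, at percentiles of 100, 100 and 99.5, and apoeb (g15956) was 21.9-fold higher (21.2 to 22.6).

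Beside these groups the immune list had a median of 1.92 (percentile 100, 59 members), with 21 members at least 4-fold higher and 0 lower. The phagocyte integrin itam was 50.9-fold higher (33.2 to 82.5), lysozyme C, lysc, 75.3-fold higher (41.9 to 151) and lysozyme G, lyg, 25.1-fold higher (19.1 to 33.5). The epithelial list had a median of 1.05 (percentile 100, 22 members), the endothelial list 0.84 (percentile 99.4, 12 members), the erythrocyte list 0.88 (percentile 99.9, 14 members) and the hepatocyte list 0.51 (percentile 97.8, 13 members). Within the last, alpha-2-macroglobulin, a2mg, was 10.6-fold higher (9.90 to 11.4) and the copper carrier ceruloplasmin, ceru, 15.5-fold lower (12.1 to 19.99). Of the epithelial members 4 were at least 4-fold higher and 1 was lower. The lower one was the keratin k1c18 (g7586), at 164 CPM in the yellow and 22.4 CPM in the matured library. The endothelial list had 0 members at least 4-fold higher by the ratio after adding 1 CPM, and its member cadh5 was 5.25-fold lower (4.35 to 6.37) without that addition. The smooth muscle list had a median of 0.01 (percentile 68.4, 35 members), and -0.01 under the DESeq2 scaling. Of its members 7 were at least 4-fold higher, including desm at a bound of at least 131-fold. In the authors' deposited table, 66 genes in silver versus yellow, 93 in matured versus silver and 128 in matured versus yellow had an adjusted p-value under 0.1. Of these genes in the authors' deposited table, 48, 63 and 97 were past the 4-fold rule used here.

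**Figure D2:**
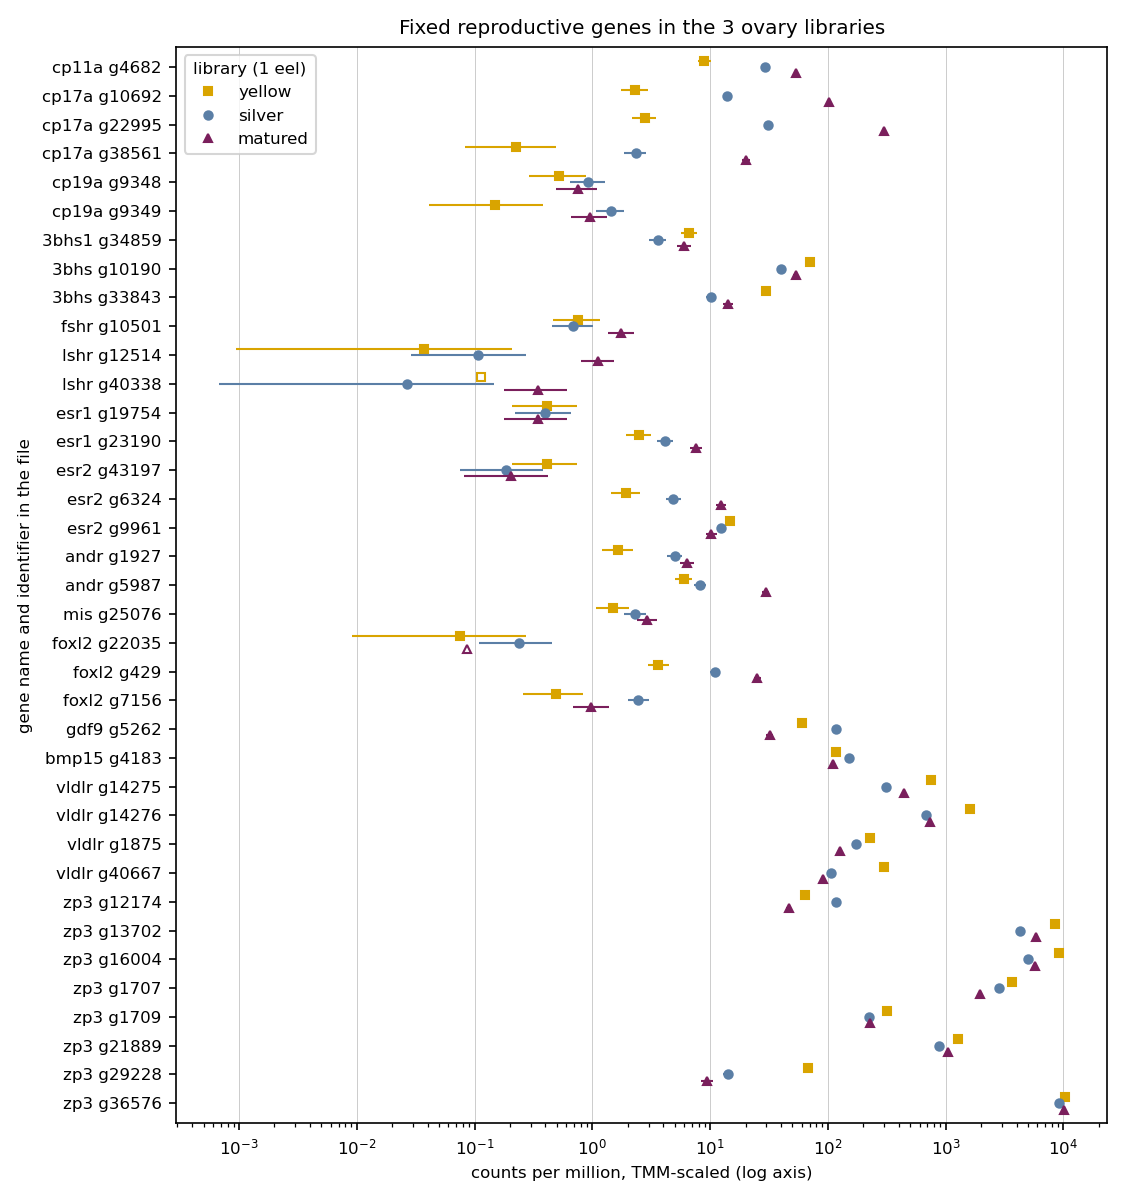
CPM on a log axis for reproductive genes fixed in advance, in the yellow (squares), silver (circles) and matured (triangles) library, 1 eel each, with bars for the 95% Poisson counting interval and open symbols at the floor of 3 counts where no read was found. The cp17a row g22995 goes from 2.78 CPM in the yellow to 31.1 in the silver and 302 in the matured library, and the most abundant zp3 row (g36576) lies between 9209.6 and 10213 CPM in the 3 libraries.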

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

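Unique reads, the authors' deposited fold, the most abundant rows left out and the length trend removed were chosen only after the results were seen; the other alternatives were planned. No paired analysis was possible because each stage has 1 eel and no test was made. Under DESeq2 size factors, unique reads, the authors' fold, the rows left out, a pseudocount of 0.1 CPM and an interval beyond 4-fold, each count of higher or lower genes stayed within 1.5 times its main value, and no named gene past the 4-fold rule changed direction under DESeq2 factors, library totals or RPKM. The log2 ratios of 115 of 159 named genes in matured versus silver, with library totals and also with RPKM, and of 98 of 158 in matured versus yellow with RPKM lay outside their counting interval.

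The counts that moved further were these. A pseudocount of 5 CPM, which by construction shrinks low genes, gave 214 higher and 68 lower in silver versus yellow, 100 and 326 in matured versus silver, and 149 and 132 in matured versus yellow. A 2-fold threshold, which is looser by construction, gave 2318 and 1386, 1212 and 2739, and 1426 and 1933, which turned the balance in matured versus yellow to more lower genes. A minimum of 1 CPM gave 671 higher in matured versus yellow. Library totals alone gave 444 higher and 327 lower in matured versus silver, by leaving out the composition factors, of which those of the silver (0.910) and matured (1.15) libraries both enter. The authors' RPKM values gave 312 lower in silver versus yellow, and 433 higher and 318 lower in matured versus silver; the cause was not tested.

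Of 28 lists, 15 stood apart in silver versus yellow, 14 in matured versus silver and 15 in matured versus yellow. With the length trend removed 9 stood apart in silver versus yellow, 8 of the 15 and 1 new. With members of at least 10 CPM, which 26 lists had in sufficient number, 9 did in matured versus silver, 8 of the 14 and 1 new. Of the other 6, 3 moved inside the range, 2 changed sign and the endothelial list had too few members. In silver versus yellow 5 of the 15 moved inside the range with RPKM (steroid synthesis, ovarian somatic, meiosis, collagens and erythrocytes), 5 with members of at least 10 CPM (ovarian somatic, meiosis, cholesterol synthesis, apoptosis and ion transport), 3 with a pseudocount of 5 CPM, 2 with one of 0.1 CPM, 2 with the authors' fold, and 1 each with library totals and the rows left out. In matured versus silver 1 did so each with library totals, RPKM and a pseudocount of 5 CPM. In matured versus yellow 3 did with members of at least 10 CPM (ovarian somatic, erythrocytes and hepatocytes), 2 each with RPKM and the length trend removed (endothelium and hepatocytes both times), and 1 each with a pseudocount of 5 CPM, unique reads and the rows left out. Some medians changed sign. With members of at least 10 CPM, which are fewer, the erythrocyte median was -0.49 in silver versus yellow, the ovarian somatic (-0.32) and heat shock (-0.036) medians in matured versus silver and the reference gene median (-0.14) in matured versus yellow turned negative. The oxidative phosphorylation median in matured versus silver became 0.26 with library totals, 0.26 with RPKM and 0.013 with the length trend removed, and the reference gene median in matured versus yellow became -0.0087 with that trend removed. Depth limits genes under about 10 CPM, where counting intervals are wide, as for lshr and cp19a.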

Other observations

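The tests of an explanation reported here were chosen only after the results had been seen.

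Several genes were higher in the silver library than in both others. The fatty acid carrier fabp4 was at 394 CPM in the yellow, 1527 in the silver and 219 in the matured library, the transcription factor sox3 (g1675) at 668, 2557 and 646 CPM, and nano3 at 217, 559 and 95.04 CPM. The ubiquitin-conjugating enzyme ube2c, which helps cells leave mitosis, was at 407, 1305 and 454 CPM. Marker lists of nerve and glia had medians of -0.02, 0.26 and 0.13 over 10 members in silver versus yellow, matured versus silver and matured versus yellow. Those of skeletal muscle were -0.01, 0.35 and 0.25 over 13 members, and those of adipocytes -0.15, 0.18 and 0.21 over 19 members, all inside the central range of random lists. Within the adipocyte list the nuclear receptor pparg was at 3.42, 1.86 and 13.9 CPM.

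Immune, collagen, matrix enzyme and epithelial lists stood higher in the matured than in the yellow library and the oocyte list lower. Their medians of the log2 ratio of counts differed from the oocyte median by 1.97 or more (matrix enzymes, bootstrap interval over members 0.97 to 2.98, widened for 4 comparisons). No factor per library can change such a difference. The lists were chosen because they stood on opposite sides, so this gap was fixed in advance and is no test of the scaling. Under the 5 scalings compared, the immune median stayed between 1.83 and 2.10 and the oocyte median between -0.71 and -0.45, so the direction of each held. Blood left in the tissue is argued against as the main source of the immune gain, since 6 globin rows gained 29.4 CPM, or 7.59% of the 387 CPM gained by the immune list, under a limit of 10%. The 387 CPM are a net value, since the 47 immune members under 10 CPM in the yellow library gained 644 CPM and the other 12 lost 257 CPM. The immune rows counted were changed after a first run. The globin rows still rose from 11.5 CPM in the yellow to 40.9 CPM in the matured library, and the erythrocyte list stood above random lists (percentile 99.9), so some added blood is not excluded. A lower share of oocyte RNA that raises every other cell type alike was tested on members under 10 CPM in the yellow library, which are 47 of the 59 immune members. Their immune median exceeded that of nerve and glia, with 7 members, by 1.72 (bootstrap interval over members 0.41 to 2.78, widened for 3 comparisons). The immune list had the highest matured versus yellow median of all lists, so a gap above another list was partly fixed by that choice. Rows near silent in the yellow library passed the limit of 1 CPM on average only through a higher value in another library. The gap therefore cannot decide for or against a lower oocyte share. The immune median exceeded the endothelial median by 0.77 (-0.69 to 2.92) and the smooth muscle median by 1.21 (-0.67 to 3.16), so a lower oocyte share may still account for the part these types have in common. A difference between the life stages stays open and was not tested.

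In silver versus yellow 15 lists stood apart, and the log2 ratio also followed transcript length, with a median of -0.26 in the shortest of 10 equal classes of genes and 0.17 in the longest. With that trend removed, the oocyte, egg coat, apoptosis, oxidative phosphorylation and immune lists stayed apart with bootstrap intervals over members that excluded the median of random lists. This argues against length as the whole cause for these lists, of which the oocyte and egg coat lists share zp rows. Reference genes went from -0.27 to -0.38, and the trend on their members, 0.13 (0.10 to 0.17), pointed the other way, which argues against length as the cause of their lower median. Their interval with the trend removed (-0.53 to 0.27) included the median of random lists, so that lower median is itself uncertain. Lipoprotein uptake went from -0.27 (-0.35 to -0.09) to -0.11 (-0.31 to 0.04) and collagens from 0.20 (-0.07 to 0.36) to 0.09 (-0.12 to 0.28), both inside the range, so a trend of the log2 ratio with transcript length may account for these 2. For the other 7 its part cannot be told apart: steroid synthesis (0.40, percentile 97.6, -0.08 to 1.22) and ovulation and prostaglandins (0.54 to 0.69, percentile 99.9, -0.17 to 1.44) kept their side with intervals that include the random median, while cholesterol synthesis (0.43, percentile 97.0), meiosis (0.49, percentile 95.5), ion transport (0.20, percentile 95.3), erythrocytes (0.47, percentile 96.96) and ovarian somatic genes (0.27, percentile 90.5) moved inside the range with most of their median left. With 1 eel per stage, the individual eel, its lake or its season in place of its stage cannot be told apart. In matured versus yellow the median log2 ratio also rose with transcript length, from -0.18 in the shortest class to 0.24 in the longest. With that trend removed, the endothelial and hepatocyte lists moved inside the range, as given above.

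Among the 15 most abundant rows of the matured library, 6 without a protein name were 5.79-fold to 52.1-fold higher than in the yellow library and took 7.35% of the reads of the matured library, against 0.572% in the yellow library. Unnamed rows among the 15 that were lower in the matured library were g45425, at 24687 CPM in the yellow and 5306 CPM in the matured library, and g452, at 18401 and 6389 CPM. One of the 6 higher rows, g43895, is described as cytochrome b, and the 6 were chosen after their values were seen. At least 99.5% of the reads of each of the 6 rows were unique alignments, which argues against reads shared with other copies present in the sequence the authors aligned to. Copies missing from that sequence or merged in it could not be seen, so shared reads are not excluded in general. More mitochondria, with nuclear and mitochondrial genes raised alike, would raise the nuclear oxidative phosphorylation list as far as these rows. The median of that list was 0.22 (bootstrap interval over members 0.01 to 0.46), under a limit of 1 set after the values were seen, which argues against an equal rise. The list still stood above random lists (percentile 100), so a smaller or unequal rise stays open. Of these rows only g43895 has a description. What these rows encode was not analysed here, and a difference between the stages stays open.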
